A study of Mus musculus with 20 samples.

How the data were processed

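Tail genomic DNA of 10 C57BL/6JNrs mice of one family (the labels' strain field reads C57BL/6) was compared with DNA of 1 reference male by array comparative genomic hybridisation, which reads the copy number of a sample from the ratio of 2 dyes at each probe. The family held a father, a mother and 8 progeny. Each mouse was hybridised on 2 arrays with the dyes exchanged, which made 20 arrays on 3 slides. The father, the mother, progeny 1 and progeny 2 were on slide 1, progeny 3 to 6 on slide 2, and progeny 7 and 8 on slide 3. The 2 arrays of a mouse shared their DNA extracts and counted as 1 replicate, so every spread between them was technical. DNA was extracted with an automated kit and labelled under protocol version 4.0.8, per the labels' protocols. The sex of the progeny is not given in the labels.

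The labels conflict on the father. The series title speaks of males exposed to 0.05 mGy of gamma rays per day for 400 days, and the samples carry that dose in their names. A sentence of the design text calls the male of this family non-irradiated. The father's exposure is therefore not settled here, and no comparison below rests on it. An unexposed family was not among the samples used here.

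The array was a custom design for a second screen. According to the design text, its probes were set densely around loci that had shown a difference in a first genome-wide screen of autosomes in such families. The loci are therefore not a random sample of the genome, and counts of differences are not rates per genome. Positions are those of the mm9 build, per the file headers.

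The deposited scanner files were made with Agilent Feature Extraction 10.7.1.1. They hold processed signals as intensity, background-subtracted, spatially detrended and dye-normalised with linear factors, per the file headers. They also hold median spot and median local background signals as intensity with no correction, per the file headers. A further deposited column holds log10 ratios of red (Cy5) over green (Cy3) processed signals, per the file headers. The authors' value table holds log2 ratios with scale, direction and centring unstated. Set against the scanner values, every column of this table was on the log2 scale and ran as reference over animal. After the sign was turned, 100% of spots in each column equalled the scanner ratio within 0.05. Its columns were not centred, with medians from -0.01 to 0.02, and how they were made is not given in the sources used here.

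Each array had 29952 spots, of which 3924 were control spots and were left out. The remaining 26028 spots carried 22010 probes, and spots of one probe were averaged. There were 21959 autosomal, 48 X and 3 Y probes. Spots with an outlier mark in the files, 77 to 133 per array, were left out. No spot was saturated (0 on every array). Runs of probes with no gap over 20 kb were taken as tiles. Of 2891 tiles, 713 had 3 or more probes and together held 19799 probes, with a median spacing of 107 bp. Between 93.4% and 98.0% of spots per array were well above background in both channels, lowest on slide 3. The number of arrays limits the precision of every value.

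Log2 ratios were formed from the processed signals, turned to animal over reference, and centred on each array's median. This direction is the opposite of that in the authors' value table. Intervals were called on the mean of a mouse's 2 arrays with an interval score written for this purpose. The score was the mean of consecutive probes times the square root of their number over the noise. The noise was the scaled median absolute deviation of adjacent-probe differences. An interval needed a score of 6, at least 3 probes, and a mean of at least 0.25 in size and of one sign in the dye-swap mean and in each of the 2 arrays. Intervals of one sign that shared a probe were merged across mice into regions. The same rule was run on the part of the signal that changes sign with the dyes, after each probe's median was taken off, to count calls where copy number should cancel.

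Differences between mice at regions were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per mouse and a dye term, and Benjamini-Hochberg adjustment over all regions and progeny at 0.05. The same model was fitted per autosomal probe against the reference, with a size of at least 0.25. Progeny were compared with parents over all probes with limma on 1 value per mouse. Transmission was tested with an exact two-sided binomial test against 0.5, with exact 95% intervals. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

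The procedures were tested on simulated data built from these arrays. The interval rule recovered 40.0% of planted intervals of 3 probes with a size of 0.30, and 72.5% of those with 5 probes. It recovered 100% of those with 25 probes, and 100% of all planted intervals with a size of 0.60 or more. It made 1 false call in 16 simulated mice. In these simulations every probe of an interval was shifted equally, and noise was drawn separately for each probe and array. The rates therefore do not describe calls carried by 1 probe, as at 47 of the 76 regions called below. At a size of 0.33, limma recovered 76.0% of planted probe differences in the father and 89.0% in the comparison of progeny with parents. That comparison was simulated with every progeny shifted and with technical spread alone, and it made 10 false calls. At called regions limma recovered 76.0% of planted differences of 0.30 in progeny 3.

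These choices, and most alternatives, were made before the data were examined. Named regions were every region called in progeny and no parent, then regions called in exactly 1 parent by mean size, then the 10 largest of the others, at most 25 in all. That gave 20 regions of the first kind and 5 of the second. Other regions named in the text were chosen after their values were seen. Alternatives covered the score threshold, the number of probes, the minimum mean, the tile gap, each dye orientation alone, normexp background correction with an offset of 50, the authors' value table, dim probes, centring, merging, the slide, the dye term and leaving out a parent. Alternatives chosen after seeing the data were the removal of each probe's dye bias, leaving out progeny 6, a test against each parent on its own, the mice of slide 1 alone, and a rule on the median of an interval's probes. The files have no mean spot signal, so normexp used median signals.

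The files carry no gene names and no annotation of the mm9 build was at hand, so regions are given by position alone. Counts of regions in gene lists fixed beforehand were not run for that reason. A correction for the GC content of probes was not run, as no mm9 sequence was at hand.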

Results

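Copy number was measured in a family of 10 mice, a father, a mother and 8 progeny, each against the same reference male. Every mouse had 2 arrays, with the dyes exchanged between them. The 22010 probes lay mostly in dense tiles around loci picked in an earlier screen, with a median of 26 probes and a median span of 3428 bp in tiles of 3 or more. Of these probes, 19694 were well above background in both channels on all 20 arrays. Each mouse is 1 replicate, so errors given for a single mouse are standard deviations between its 2 arrays and describe the measurement only. All signed values are log2 of animal over reference, the opposite direction to the authors' value table.

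The first question was which loci differed in copy number from the reference in each mouse. The father and progeny 1, 3, 4 and 5 shared a gain on chromosome 4, the widest difference in the family. The mother and progeny 7 and 8 shared many short losses spread over the autosomes and a wide loss on chromosome 3. Progeny 2 and 6 carried neither as a call. In all, 197 intervals were called, 33 gains and 164 losses, which merged into 76 regions. The balance depended on the rule, with 191 gains and 91 losses at a mean of at least 0.4, where 182 of the gains lay inside the chromosome 4 gain, and 292 gains and 232 losses with the animal in Cy3 alone. Under the rule set beforehand, progeny 8 had the most calls, 56, and progeny 1 the fewest, 3. The father had 3 gains and 2 losses, and the mother 4 gains and 49 losses. Progeny 7 had 5 gains and 50 losses and progeny 8 had 5 gains and 51 losses. Progeny 2, 3, 4, 5 and 6 had 5, 6, 6, 4 and 4 calls. With probe dye bias removed, an alternative chosen after seeing the data, the mother had the most calls, 62, and progeny 6 the fewest, 3.

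Most called regions rested on few probes. Of the 76 regions, 47 had exactly 1 probe past 0.25 in size, 21 had 2, and 8 had 3 or more. Where 1 probe carried the region, its median value was -1.31. When the median of an interval's probes also had to reach 0.25 in size, a rule chosen after seeing the data, 66 calls and 29 regions were left. Of these regions, 11 were in progeny without a parent, 1 of them a loss of the mother under the first rule. Without the condition on each single array, the rule on the mean gave 299 calls on the dye-swap mean. Run the same way on the dye-dependent part of the signal, it gave 36 calls, 18 of them in progeny 6.

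**Figure D1:**
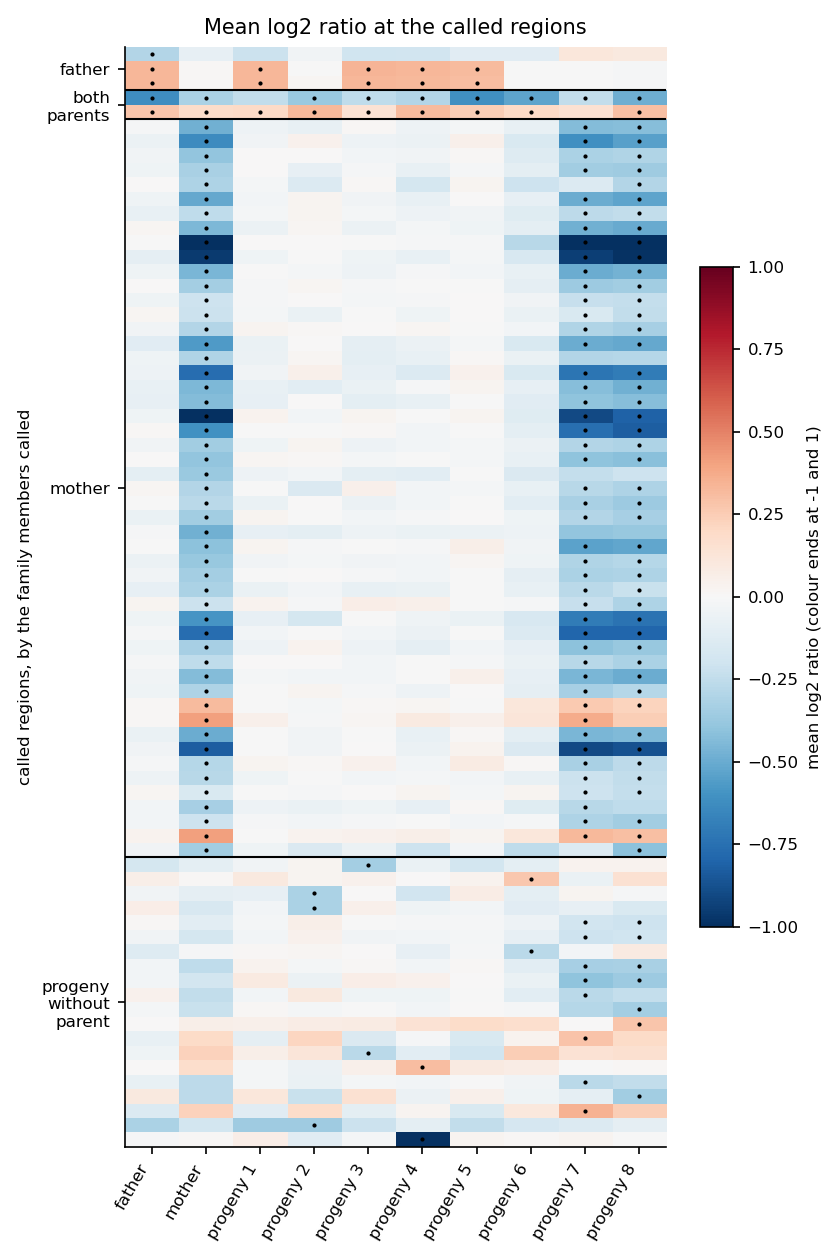
Each line across is one of the 76 called regions and each column a mouse; colour gives the mean log2 ratio to the reference, and a dot marks a call. Of the 51 regions of the mother, 48 recur as calls in progeny 7 or 8 and none in the other progeny, while the chromosome 4 gain of the father recurs in progeny 1, 3, 4 and 5.

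The gain on chromosome 4 was called as a pair of regions on either side of a gap without probes, and was chosen for description after its values were seen. The first spanned 101109089 to 101215058 with 537 probes, and the second 101237071 to 101271028 with 270 probes. Over the first region the father measured 0.33 ± 0.02 (SD of 2 arrays). Progeny 1 measured 0.33 ± 0.03, progeny 3 measured 0.34 ± 0.05, progeny 4 measured 0.33 ± 0.05 and progeny 5 measured 0.31 ± 0.04. The mother measured 0.01 ± 0.03. Progeny 2, 6, 7 and 8 all lay between -0.01 and 0.00. Over the second region the father again measured 0.33, and progeny 1, 3, 4 and 5 measured 0.33, 0.33, 0.33 and 0.30. With limma, progeny 2 minus the father was -0.33 over the first region (SE 0.03, adjusted p = 4.8e-06), and progeny 1 minus the father was 0.00 (SE 0.03, adjusted p = 0.998). The gain was called in 4 of 8 progeny (exact two-sided binomial p = 1 against a share of 0.5).

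**Figure D2:**
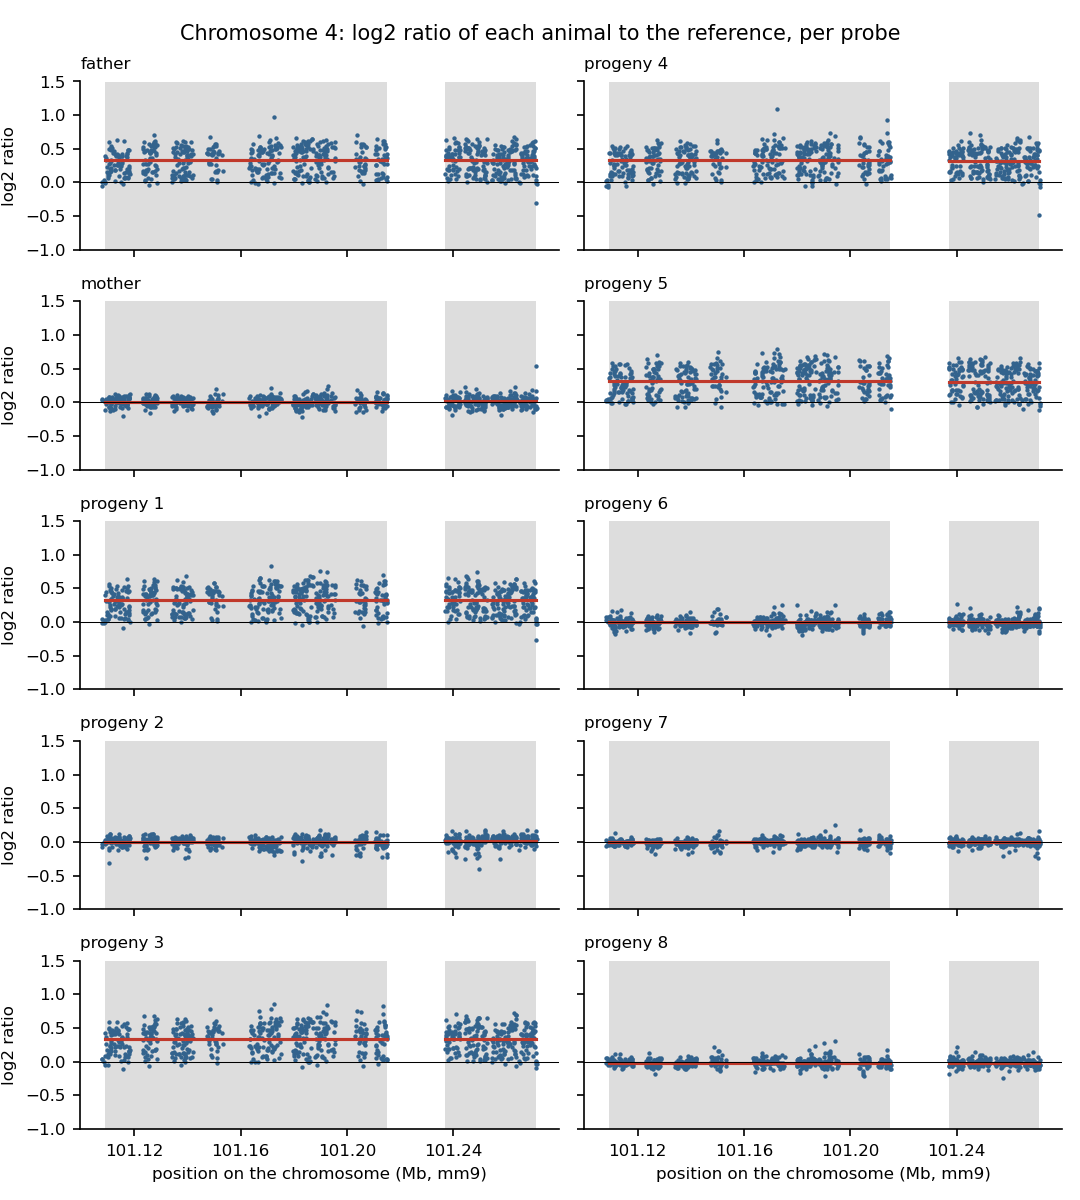
Points are probes on chromosome 4 by mm9 position in Mb, with the log2 ratio of one mouse to the reference (mean of 2 arrays) on the vertical axis; grey marks the called regions and the red line their mean. The father and progeny 1, 3, 4 and 5 sit near 0.33 and the other mice near 0.

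The father had 1 further region that the mother lacked, also named after its values were seen. It was a loss of 4 probes on chromosome 1 from 179510641 to 179511128, at -0.29 ± 0.05. No progeny was called there, although progeny 1 measured -0.22, progeny 3 measured -0.20 and progeny 4 measured -0.20.

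Of the regions called in the mother and not the father, 48 were losses on 17 autosomes and 3 were gains. Progeny 7, progeny 8 or both were called at 48 of these 51 regions, and no other progeny was called at any of them. Exactly 44 regions were called in the mother, progeny 7 and progeny 8. The loss on chromosome 3 from 25416456 to 25447093 was the widest, with 83 of its 85 probes past 0.25 in size. It measured -1.65 ± 0.01 in the mother, -1.49 ± 0.00 in progeny 7 and -1.52 ± 0.03 in progeny 8. The father measured 0.00, and progeny 1 to 5 lay between -0.02 and 0.01. Progeny 6 measured -0.28 ± 0.43, with a median of -0.58 on the array with the animal in Cy3 and 0.04 on the array with the animal in Cy5. With limma, progeny 7 minus the father was -1.49 (SE 0.12, adjusted p = 4.8e-06), and progeny 7 minus the mother was 0.16 (SE 0.12, adjusted p = 0.292). Leaving out progeny 6, whose 2 arrays widened this error, was an alternative chosen after seeing the data. With limma, the difference from the mother was then 0.16 in progeny 7 (SE 0.03, adjusted p = 0.00157) and 0.13 in progeny 8 (SE 0.03, adjusted p = 0.00478). These errors hold only the spread between the 2 arrays of a mouse. The mother was on slide 1 and progeny 7 and 8 on slide 3, so an effect of the slide cannot be told apart from this difference.

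**Figure D3:**
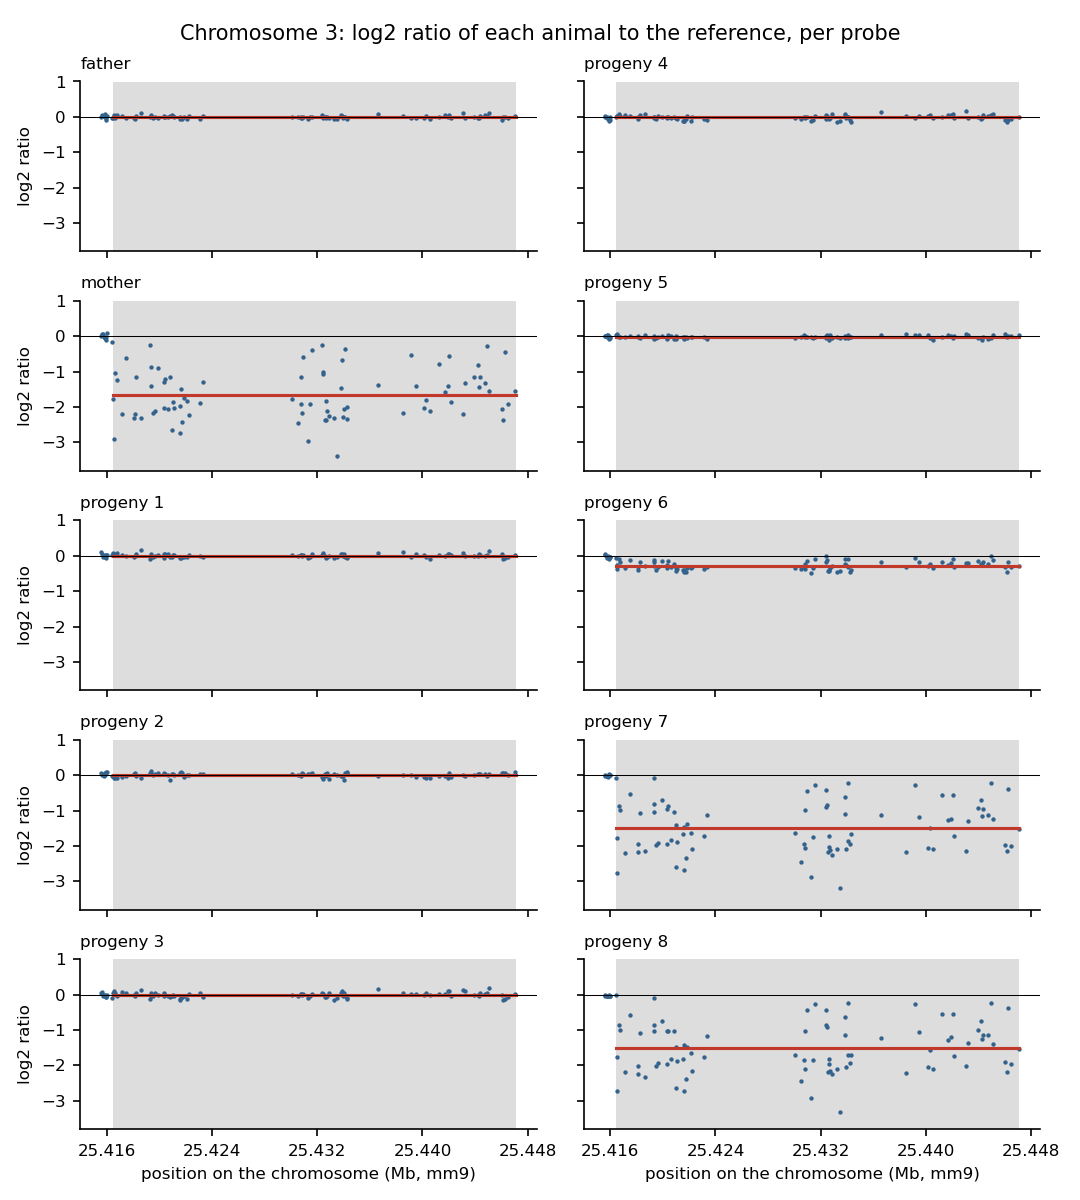
Points are probes on chromosome 3 by mm9 position in Mb, with the log2 ratio of one mouse to the reference (mean of 2 arrays) on the vertical axis; grey marks the called region and the red line its mean. The mother, progeny 7 and progeny 8 lie between -1.65 and -1.49 on average, progeny 6 at -0.28 and the other mice near 0.

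The other named losses of the mother were short. On chromosome 7, the loss from 18816858 to 18817395 measured -1.03 in the mother, -0.91 in progeny 7 and -0.81 in progeny 8. A second on chromosome 7, from 126944605 to 126944931, measured -0.60, -0.75 and -0.83 in the same mice. On chromosome 13, the loss from 77818414 to 77818665 measured -0.76, -0.80 and -0.79. On chromosome 6, the loss from 104241190 to 104241486 measured -0.76, -0.73 and -0.70, carried by 1 probe at -2.87. Of the 51 regions, 36 had 1 probe past 0.25 in size. Over the lowest probes of the 47 losses other than the one on chromosome 3, the median was -1.43 in the mother, -1.41 in progeny 7 and -1.43 in progeny 8. It was -0.28 in progeny 6, -0.11 in the father, and between -0.11 and 0.03 in progeny 1 to 5. The widest gain of the mother, named after its values were seen, lay on chromosome 15 from 75797574 to 75799045 with 19 probes. It measured 0.32 ± 0.01 in the mother, 0.26 ± 0.02 in progeny 7 and 0.23 ± 0.02 in progeny 8.

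The X and Y probes gave a scale for these values, and progeny 7 and 8 lay near the mother on X and between the parents on the Y median. The mother, against a male reference, had a median of 0.75 over 48 X probes and -0.98 over 3 Y probes. Progeny 7 measured 0.60 on X and -0.49 on Y, and progeny 8 measured 0.64 on X and -0.41 on Y. At the lowest of the Y probes the mother measured -3.22, progeny 7 measured -2.39 and progeny 8 measured -2.38. The father and progeny 1 to 5 lay between -0.02 and 0.01 on X and between -0.06 and 0.03 on Y. Progeny 6 measured 0.21 on X and -0.32 on Y. Its X value was 0.47 on the array with the animal in Cy3 and -0.06 on the array with the animal in Cy5.

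**Figure D4:**
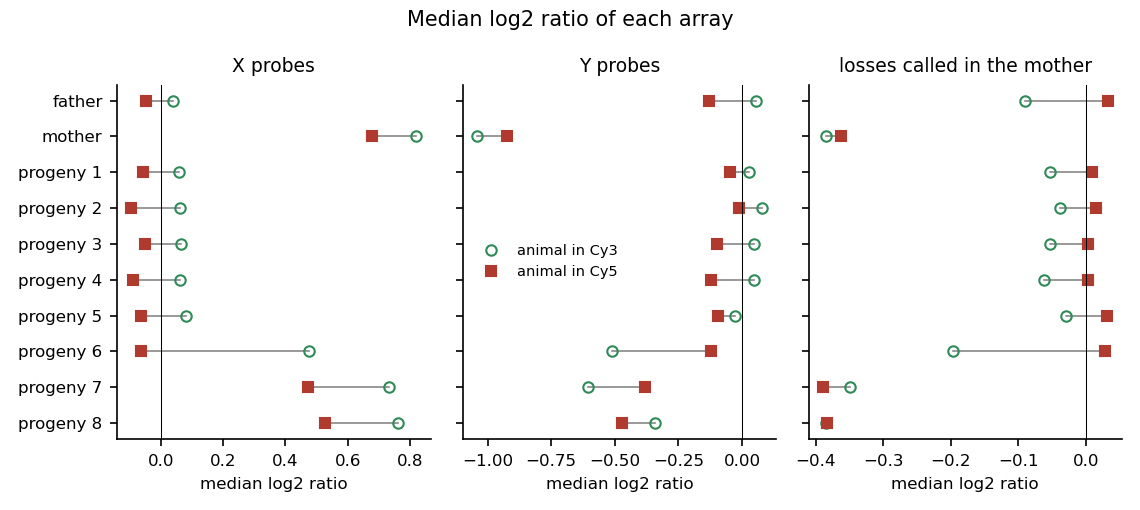
Each symbol is the median log2 ratio of one array over X probes, Y probes or the losses called in the mother, for each mouse; open circles have the animal in Cy3 and filled squares in Cy5. The 2 arrays of progeny 6 lie apart in every panel, at 0.47 and -0.06 over X.

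Only 2 regions were called in both parents, and both were named after their values were seen. A loss on chromosome 9 from 74329945 to 74330215 was called in every mouse but progeny 1. It measured -0.62 in the father, -0.32 in the mother and -0.25 in progeny 1. A gain on chromosome 13 from 95705166 to 95707908 was called in every mouse but progeny 7. It measured 0.28 in the father, 0.18 in the mother and 0.16 in progeny 7, and rested on 1 of its 5 probes.

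Transmission was asked of all 54 regions called in exactly 1 parent. Progeny were called at 100 of 432 chances, 23.1% (95% exact interval 19.3 to 27.4; exact two-sided binomial p = 3.8e-30 against a share of 0.5). The regions are not independent of one another, since 44 of them were called in the same 2 progeny. The share of 0.5 assumes a variant heterozygous in that parent. Of the 54 regions, 51 were the mother's, and independent passing of heterozygous variants is argued against for her losses below. The p-value is therefore no measure of a low rate of transmission. For one such region the share of 2 of 8 gives an exact p of 0.289. A region called in 0 of 8 progeny gives an exact p of 0.00781, which was 0.105 after Benjamini-Hochberg adjustment over the 54 regions. A missing call did not always mean a value near 0, as at the 3 losses of the mother where no progeny was called, named after their values were seen. On chromosome 6 from 77885163 to 77885276 the mother measured -0.30, progeny 7 measured -0.29 and progeny 8 measured -0.29. On chromosome 9 from 4511804 to 4512210 these values were -0.37, -0.24 and -0.21, and on chromosome 10 from 109080124 to 109080245 they were -0.48, -0.39 and -0.38 (SD of 2 arrays up to 0.29).

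The study's main question was whether progeny carried copy number differences that neither parent had. There were 20 regions called in progeny and in no parent, 5 gains and 15 losses, on 12 chromosomes. They were small, with a median of 3 probes, a median length of 229.5 bp and a median size of 0.32. Of these, 16 were called in 1 progeny, 11 were called only in progeny 7 or 8, and 10 rested on 1 probe past 0.25 in size. The widest, on chromosome 12, spanned 7998 bp. The count depended on the calling rule, with 4 regions when at least 5 probes were required, 9 at a mean of at least 0.4, 11 among probes well above background, 12 with normexp and 89 at a mean of at least 0.15.

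In progeny 2, a loss on chromosome 5 from 41411070 to 41411349 measured -0.32 ± 0.01, against -0.03 in the father and -0.09 in the mother. A loss on chromosome 6 from 83774797 to 83774919 measured -0.32 ± 0.00, against 0.07 and -0.16. A loss on chromosome 16 from 94792698 to 94792917 measured -0.36, against -0.31 in the father and -0.18 in the mother. In progeny 3, a loss on chromosome 2 from 100379406 to 100379558 measured -0.34, against -0.17 in the father and -0.10 in the mother. A loss on chromosome 11 from 110393764 to 110393907, also in progeny 3, measured -0.27 where the mother measured 0.23. This call did not pass the test against each parent on its own, given below. In progeny 4, a gain on chromosome 12 from 46868498 to 46876495 measured 0.31 ± 0.06, against 0.18 in the mother. The lowest value of the list was a loss on chromosome 19 from 53996320 to 53996558, also in progeny 4, at -1.25 ± 1.31. Its means were -2.18 on the array with the animal in Cy3 and -0.33 on the other, and its 1 probe well above background on all arrays measured 0.08. In progeny 6, a gain on chromosome 2 from 127178150 to 127178348 measured 0.27, against 0.06 in the father and 0.01 in the mother. A loss on chromosome 7 from 47257544 to 47257875, also in progeny 6, measured -0.27, against -0.13 and -0.01. The 2 arrays of this mouse disagreed elsewhere, and neither call passed the test against each parent on its own.

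Progeny 7 and 8 were both called at a loss on chromosome 10 from 55798224 to 55798548, at -0.40 ± 0.13 and -0.37 ± 0.15, where the mother measured -0.18. Both were called at a loss on chromosome 10 from 39061697 to 39061792, at -0.33 and -0.32, where the mother measured -0.25. A loss on chromosome 6 from 86064075 to 86064591 was called in both as well, at -0.19 and -0.21, where the mother measured -0.10. So was a loss on chromosome 7 from 20563670 to 20571067, at -0.20 and -0.20, where the mother measured -0.17. Progeny 7 alone was called at losses on chromosome 10 from 81100106 to 81100251 (-0.27, mother -0.25) and on chromosome 13 from 43680199 to 43680413 (-0.27, mother -0.26). Progeny 8 alone was called at losses on chromosome 11 from 6942555 to 6942707 (-0.34, mother -0.22) and on chromosome 14 from 109470021 to 109470365 (-0.35, mother -0.26), and at a gain on chromosome 11 from 42077837 to 42078135 (0.28). A call in 1 of these 2 mice did not mean a value near 0 in the other. Progeny 7 measured -0.29 ± 0.06 at the loss from 6942555, and progeny 8 measured -0.24 ± 0.14 at that from 81100106. Gains in progeny 7 on chromosome 11 from 89489244 to 89489739 and on chromosome 15 from 63117083 to 63117279 measured 0.29 and 0.35, where the mother measured 0.19 and 0.23.

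With limma, 21 of the 24 calls in these 20 regions differed from the mean of both parents after adjustment, in regions that had been chosen because progeny were called there. Where the parents differ, a mouse with the value of 1 parent differs from their mean too. At the chromosome 10 loss from 39061697, called in progeny 7 and 8, the father measured -0.03 and the mother -0.25. Passing this test therefore does not show a difference that neither parent had. Against each parent on its own, a test chosen after seeing the data, 5 of the 24 passed. These were the losses of progeny 2 on chromosomes 5 and 6, and that from 55798224 on chromosome 10 in progeny 7 and 8. The last was the chromosome 11 loss from 6942555 in progeny 8, where progeny 7 measured -0.29 without a call. Among them, only the chromosome 6 loss was still called under the rule on the median of an interval's probes. Its probe median was -0.40. That of the chromosome 5 loss was -0.11, and that of the chromosome 11 loss was -0.06. For the chromosome 10 loss it was -0.04 in progeny 7 and -0.08 in progeny 8. For the chromosome 6 loss, progeny 2 minus the father was -0.39 (adjusted p = 2.4e-04) and progeny 2 minus the mother was -0.16 (adjusted p = 0.0294). For the chromosome 5 loss these differences were -0.28 (adjusted p = 0.0216) and -0.23 (adjusted p = 0.0260). The spread in both tests is that between arrays of one DNA. In the test against the mean of both parents, leaving out the father gave 9 of the 24 in place of 21.

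Progeny were also compared with parents probe by probe, with the mouse as the replicate. No autosomal probe passed in limma (0 of 21959, with 616 at an unadjusted p under 0.05). With the slide as a block the count was 0 as well, with 1149 at an unadjusted p under 0.05. Among the mice of slide 1 alone it was 0, with 518. With no difference at all, a share of about 0.05 of probes would lie under that limit. None of these unadjusted counts stands well above that share. This comparison asks for a shift that the progeny share. It cannot exclude differences in 1 progeny, as called at 16 of the 20 regions above.

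Counted without the interval rule, probes that differed from the reference followed the same family split. Limma called 515 higher and 12 lower probes in the father. Progeny 1, 3, 4 and 5 had 513, 559, 518 and 474 higher probes. The mother had 204 lower and 43 higher probes, progeny 7 had 178 lower and 49 higher, and progeny 8 had 208 lower and 29 higher. Progeny 2 had 70 lower and 2 higher probes, and progeny 6 had 21 lower and 11 higher. Summed over mice this made 3471 calls, 78.2% of them higher. Most of the higher calls came from the father and progeny 1, 3, 4 and 5, the mice called at the chromosome 4 gain. A probe was counted once per mouse, so this share does not describe loci.

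Before dye effects were removed, the 2 arrays of a mouse did not agree across probes, which are not independent replicates. The median Pearson r was -0.18 over the 10 mice, from -0.48 to 0.34. Spearman correlation was negative in every mouse, with a median of -0.44, from -0.64 to -0.29. After each probe's common dye bias, its median over the same 10 mice, was taken off, the median Pearson r was 0.54. Pearson r was then lowest in progeny 6 at -0.06 and highest in the mother at 0.83. With that bias removed, 71 of the 76 regions were called again.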

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

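All tests of explanations in this part were chosen only after the results were seen. Among 38 quantities measured per progeny, 5 had 1 animal far from the other 7 by a gap test (Dixon), where chance alone gives about 1 in 20. These were 3 measures of progeny 6 and 2 regions of progeny 4. For the regions that rate does not hold, since they were chosen because this animal was called there. No biological explanation was tested for progeny 6.

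The 2 arrays of progeny 6 disagreed: calls from the dye-dependent part of the signal numbered 18 against 0 to 4 in the other progeny, the arrays correlated at -0.061 across probes after probe dye bias was removed (0.34 to 0.69 in the others), and the X value was higher by 0.54 on the Cy3 array (0.12 to 0.26). Noise of that array alone is argued against, since the chromosome 3 loss region on the Cy3 array differed from progeny 3 to 5 by -0.58, where 243 windows of 85 other probes on that array lay between -0.05 and 0.06. Another animal's DNA in place of progeny 6 is also argued against, since the share of DNA like the mother's at that region was at most 0.513 on the Cy3 array. DNA of a female mixed into that sample may account for it, with shares of 0.47 on X (95% interval 0.393 to 0.548) and 0.472 at the chromosome 3 loss (0.431 to 0.513), while the 0.426 at the other losses decides little (0.126 to 0.725, with 0.210 on the father's Cy3 array). This rests on a baseline from progeny 3 to 5 and an interval with their spread, both adopted after a first version with the father as baseline and an interval over probes alone gave 0.32 for the last set, with intervals that did not overlap.

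Of the 48 losses of the mother, 42 were called in both progeny 7 and progeny 8, on 16 autosomes. An effect of the mother's slide is argued against, since 0 of the 48 was called in progeny 1 or 2, which were on that slide. This says nothing of slide 3, which held progeny 7 and 8 alone. Variants heterozygous in the mother that passed on independently are argued against too: at the deepest loss of each of 17 autosomes, progeny 7 and 8 were each called at 14 and the other 6 progeny at 0 (exact p of the spread over all 8 progeny = 1.6e-30). The sex of the animals, with sequence like these probes on the Y chromosome of the reference male, stays open: progeny 7 and 8 lay near the mother on X (0.60 and 0.64 against 0.75) and measured -2.39 and -2.38, -0.49 and -0.41, and -0.17 and -0.21 at the 3 Y probes, where the mother measured -3.22, -0.98 and -0.16 and the father -0.08, -0.05 and -0.02. The father and progeny 1 to 5, on slides 1 and 2, lay between -0.02 and 0.01 on X and were called at none of these losses. Progeny 6, whose 2 arrays disagreed, lay at 0.21 on X with no call. The test of sex asked for slide mates without the losses. Progeny 7 and 8 were the only mice on slide 3, so that test could not have come out in favour of sex. Whether the Y chromosome holds such sequence was not analysed here.

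The loss on chromosome 19 from 53996320 to 53996558 in progeny 4 measured -1.25, where the other progeny lay between -0.12 and 0.06. Its lowest probe was well above background in both channels on 0 of the 20 arrays, so its ratio of -6.76 on the Cy3 array cannot be read as a copy number. A deletion across the region is argued against, since its other 2 probes differed by -0.065 from those of the 7 other mice where both were well above background (SD of these mice 0.056). A faulty spot on 1 array may account for the depth of the loss, as the reference channel at the lowest probe read 3793 there against 32.5 to 81.2 on the other 19 arrays, while the animal's channel read 34.8 against 34.1 to 85.0. No biological explanation within 1 probe was tested.

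The gain on chromosome 12 from 46868498 to 46876495 in progeny 4 measured 0.31, apart from the other progeny at -0.06 to 0.09, while the mother measured 0.18.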

How the results depend on the processing

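The tests with dye bias removed, without progeny 6, by the median of the probes, on slide 1 alone over all probes and against each parent on its own were chosen only after the data were seen. Of the alternative values, 103 stayed within the limits set, 49 moved and 1 reversed. The gain on chromosome 4 in the father (0.30 to 0.35) and the loss on chromosome 3 in the mother (-1.65 to -1.57) kept their direction under all alternatives run. The loss on chromosome 19 in progeny 4 reversed to 0.082 when only probes well above background were used, which left 1 of its 3 probes.

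Counts of calls and regions moved with the calling rule. In place of 33 gains and 164 losses there were 191 and 91 at a mean of at least 0.4, and 292 and 232 with the animal in Cy3 alone. In place of 197 calls and 76 regions there were 100 and 39 with at least 5 probes, 382 and 185 with a mean of at least 0.15, 299 and 134 with the dye-swap mean alone, 347 and 167 with the animal in Cy5 alone, 524 and 218 with the animal in Cy3 alone, and 66 and 29 when the median of the probes had to reach 0.25. Regions of the father (3) became 13 at a mean of 0.15, 36 at 0.4 (34 of them pieces of the chromosome 4 gain), 7 at a tile gap of 5 kb, 6 with the dye-swap mean alone, 14 in Cy5 alone, 11 in Cy3 alone and 5 with dye bias removed. Regions of the mother (51) became 31 with at least 5 probes, 81 at 0.15, 33 at 0.4 and 14 by the median rule. Regions of both parents (2) became 1 at a threshold of 8, 0 with at least 5 probes, 0 at 0.4, 4 in Cy5 alone, 11 in Cy3 alone and 1 by the median rule. Regions of progeny without a parent (20) became 4 with at least 5 probes, 89 at 0.15, 9 at 0.4, 54 with the dye-swap mean alone, 101 in Cy5 alone, 128 in Cy3 alone, 12 with normexp, 11 with probes well above background, 36 under the stricter merging rule and 11 by the median rule. Apart from the pieces on chromosome 4 and the settings that remove probes, the cause was not tested.

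Calls from the dye-dependent part of the signal, 36 in all, fell to 18 without progeny 6. Of the 24 calls in progeny without a parent, 21 passed limma against the mean of both parents, 12 without a dye term, 5 against each parent on its own, and 2 of 3 on the slide that holds both parents. Leaving out the father gave 9, the mother 16, and progeny 6 gave 21 of 22. The 3471 probe calls against the reference became 1953 without a dye term and 2286 at a size of 0.4. The share of progeny called at regions of 1 parent was 23.1%, and ranged from 18.5% under the stricter merging rule to 30.6% at a mean of at least 0.4. The comparison over all probes stayed at 0 in limma under every alternative run, with 518 to 1149 probes at an unadjusted p under 0.05. Median dye-swap r was -0.40 with normexp. No paired comparison of the groups was run, since the replicate numbers mark different mice. The correction for GC content was not run, as no mm9 sequence was at hand. Slide 3, with progeny 7 and 8, had the lowest share of spots well above background, 93.4% to 94.7%.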

Other observations

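The observations here were all chosen after the values were seen. At 2 probes in regions called in both parents, the mice fell at different levels. The probe on chromosome 13 from 95707465 to 95707524 measured 1.49 in the father, and from 1.41 in progeny 8 to 1.54 in progeny 2, with progeny 4 and 5 between these. It measured 0.87 in the mother, 0.90 in progeny 1, 0.87 in progeny 3 and 0.83 in progeny 7, and 1.09 in progeny 6. The SD between the 2 arrays of a mouse was at most 0.12 at this probe. The probe on chromosome 9 from 74330099 to 74330158 measured -1.15 in the father, -1.19 in progeny 5, -1.10 in progeny 6 and -0.86 in progeny 8. It measured -0.60 in the mother, -0.51 in progeny 1, -0.69 in progeny 2, -0.45 in progeny 3, -0.54 in progeny 4 and -0.49 in progeny 7. Its SD between the 2 arrays was up to 0.23, in the father, and 0.16 in progeny 8. No test was run on these levels.

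Outside the called regions, 17 autosomal probes reached 0.4 in size on each of the 2 arrays, with one sign, in at least 2 mice. Of these, 7 did so in the mother, progeny 7 and progeny 8, and 3 in progeny 7 and 8, where the mother's means were -0.49, -0.43 and -0.27. The deepest, on chromosome 5 from 109220847 to 109220906, measured -1.23 in the mother and -1.02 and -1.01 in progeny 7 and 8. One probe did so in the father and progeny 5, on chromosome 17 from 37986498 to 37986557, at -0.63 and -0.60. One on chromosome 10 from 97349869 to 97349928 did so in the mother (-0.59), progeny 2 (-0.47), progeny 6 (-0.47) and progeny 8 (-0.62).

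The gains of progeny 7 on chromosome 11 from 89489244 and on chromosome 15 from 63117083 had raised values in the same other mice below the calling limit. The mother measured 0.19 and 0.23, progeny 2 measured 0.21 and 0.18, and progeny 8 measured 0.19 and 0.25. The father measured -0.07 and -0.14, progeny 3 measured -0.15 and -0.10, and progeny 5 measured -0.15 at both.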
